A study of Mus musculus with 6 samples.

How the data were processed

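RNA from tongue tissue of 6 mice of 1 inducible Dek genotype was hybridised by the submitters, per the labels' protocols, as Cy3-labelled cRNA to single-colour Agilent SurePrint G3 mouse arrays. The deposited scanner files hold linear signal intensity per spot, written by Agilent Feature Extraction 11.5.1.1 per the file headers, with background already subtracted in the processed signal. The deposited series value table equals that processed signal multiplied by 1 factor per array (3.70 to 3.99), so it is on a linear intensity scale; the rule behind the factors is not given in the sources used here. Its column medians were 102.5, 94.2 and 92.7 for no DOX replicates 1 to 3 and 90.01, 97.5 and 93.7 for DOX replicates 1 to 3. Groups were taken from the treatment label of each sample and replicate numbers from the titles. The labels describe separate mice. All 6 arrays lay on 1 slide with 1 scan, so neither could be used as a block. No DOX replicates 1 to 3 and DOX replicate 1 lay in row 1 of the slide and DOX replicates 2 and 3 in row 2.

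Each array held 59305 non-control spots for 55681 probes, and 146 to 195 spots per array marked as outliers were left out. The log2 of the processed signal was averaged over the spots of a probe, and each array's 75th percentile over non-control probes was subtracted. Probe accessions were named through a RefSeq gene table of assembly GRCm38.p6; 28331 probes matched 1 gene symbol and 27350 none, and the latter are reported by probe only. The arrays were annotated on another build, so no coordinates are given. Probes were tested where they were well above background on all 3 arrays of at least 1 group, which left 30933 probes for 26256 genes and unnamed probes. The brightest probe stood for a gene; of 28 named genes with several tested probes, those of Mylpf, Rpl11 and Slc7a5 differed in sign.

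Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, without trend or robust settings), with Benjamini-Hochberg adjustment over all probes and a threshold of 0.05. In the report, ± after a log2 change is its standard error. Of 998 genes in 48 lists written before the data were examined, 996 were found in the gene table; 46 lists had at least 5 tested genes. The list of genes encoded by mitochondrial DNA (0 tested) and the sex-linked list (1 tested) were not tested. Lists were tested with camera (correlation 0.01, and again with the correlation estimated) and fry, on the 15205 gene symbols with a value on every array, since a probe without a symbol could be in no list. That background was settled after both versions had been run, and the other version is among the alternatives. Genes were named by a rule fixed before the data were examined. Dek came first, then the 12 largest rises and 12 largest falls among genes past the threshold whose groups did not overlap. Unnamed probes and Rik, Gm, LOC or accession-like symbols were counted but not ranked there. Each called list, or list holding a called gene, gave up to 4 members with the smallest p. Other lists described gave up to 2. Nr1d2, Per1, Clock, Per2, Wee1, Usp2, Hes1, Bpifa2, Klk1 and Car6 fall outside this rule and were named after their values were seen. Some genes that the rule names are not reported here.

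On simulated arrays with the fitted means and spreads of the 30933 probes of this comparison, the fit recovered 1.5% of probes changed by 0.5 on the log2 scale, 49.3% of those changed by 1 and 93.9% of those changed by 2, with 7 false calls, and made 0 calls when nothing was changed. In simulated data, camera called the 1 list shifted by 0.5 and 0 others; the simulated genes were drawn independently, so this does not test correlated genes. Alternatives covered background correction, normalization, the value table, filters, the variance model, array weights, a replicate block, the probe rule, the threshold and leaving out each array. Normexp was planned on the mean signal, which is not among the columns used here, and was run on the median signal.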

Results

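Gene expression was measured in tongue tissue of 6 mice with single-colour Agilent mouse arrays. All 6 animals carried a transgene designed to raise Dek, a chromatin protein, when doxycycline (DOX) is given. DOX is an antibiotic used to switch such transgenes. There were 3 mice without DOX and 3 mice given DOX for 2 weeks, and the comparison asks how tongue expression differs between mice given DOX and mice not given it. Between 56.0% and 58.3% of the 55681 probes on each array were well above background. No spot was saturated, and the 75th percentile of the processed signal lay between 279.7 and 302.2. The number of arrays limits the precision of each value. Every mouse had the transgene, and no transgene-free mice given DOX were analysed here, so the effects of DOX and of Dek induction are not separated by this design. The series title mentions a carcinogen, and the sample labels used here name none.

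Dek itself, measured by 1 probe (A_51_P298355), was 1.12-fold higher with DOX. The log2 difference of 0.17 ± 0.11 (SE, n = 3 and 3) did not pass the test (limma, adjusted p = 0.456). Its mean normalised log2 signal was 2.20 ± 0.10 (SD, n = 3) without DOX and 2.36 ± 0.08 (SD, n = 3) with DOX. An exact two-sided permutation test over the 20 assignments of the arrays gave p = 0.2, where 0.1 is the smallest value this design can give. The 95% interval of the fold change ran from 0.938 to 1.34. The sources used here do not give the part of the Dek transcript that the probe reads or the part that the transgene carries. A probe outside the transgene's part would not register it, so this value does not check the labels.

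Of 26256 genes and unnamed probes tested, 73 rose and 33 fell with DOX at an adjusted p under 0.05 (limma, Benjamini-Hochberg). With no filter on dim probes Nr1d1 alone passed (adjusted p = 0.0404), and the other 33 of the 34 named genes that had passed lay between 0.0508 and 0.141. Of the 73 and 33, 56 and 24 had a gene symbol. Exo1, an exonuclease, rose 5.58-fold (log2 2.48 ± 0.21, SE, adjusted p = 0.0151). Dscc1, a subunit of a PCNA loader, rose by 2.07 ± 0.12 on the log2 scale (adjusted p = 0.0111). Fignl1 rose 4.23-fold, Dtl, a receptor that targets Cdt1 for degradation, 4.02-fold, and Mcm10 3.80-fold. Mcm5, part of the replicative helicase, rose by log2 1.89 ± 0.13, and Cdc6, a helicase loader, rose 3.69-fold, with 2 of the 3 arrays without DOX well above background. The clock repressor Cry1 was 5.24-fold higher (log2 2.39 ± 0.25, adjusted p = 0.0241) and was well above background on 1 of the 3 arrays without DOX. Tph1, a tryptophan hydroxylase, rose 4.51-fold and was well above background on 2 of the 3 arrays without DOX. Ppp1r3c, which targets a phosphatase to glycogen, rose 3.86-fold. Creld2, a gene of the endoplasmic reticulum stress response, rose 3.82-fold. C2cd4b was not well above background on any array without DOX and was at least 6.22-fold higher with DOX (adjusted p = 0.0300). Normexp background correction, with an offset of 50, gave smaller log2 changes that still passed: 1.39 for Exo1, 0.68 for Dscc1, 1.49 for Fignl1, 1.07 for Dtl, 1.29 for Mcm10, 0.57 for Cdc6, 0.55 for Cry1, 0.66 for Tph1 and 0.82 for C2cd4b.

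Of the 24 genes with a symbol that fell, 12 were named by the rule, and the 2 largest fitted falls among these were those of clock genes. The clock output gene Dbp was 8.23-fold lower (log2 -3.04 ± 0.20, adjusted p = 0.0111). The nuclear receptor gene Nr1d1, also called Rev-erb alpha, was 7.41-fold lower (log2 -2.89 ± 0.13, adjusted p = 0.0050). Ndufa4l2, a mitochondrial protein gene induced in hypoxia, was 3.55-fold lower, and Bcl6b was 3.51-fold lower. The adrenergic receptor gene Adrb3 was 2.78-fold lower, Cecr2 2.72-fold lower (well above background on 2 of the 3 DOX arrays), and Ms4a4b, which is expressed in T cells, 2.71-fold lower. A further 5 of the 12 falls named by the rule ended in signals that were not well above background on any DOX array. The chemokine gene Ccl1 was at least 1.92-fold lower and Skint8 at least 1.55-fold lower. The T cell genes Cd8a and Cd247 were at least 1.69-fold and at least 1.22-fold lower, and Nckap5 at least 2.39-fold lower. Each bound sets the mean of the brighter group against the lowest signal well above background on each array of the dimmer group, or the probe's own signal where higher. These bounds apply to the processed signal alone: with normexp, Ccl1, Skint8, Cd8a, Nckap5, Cd247 and Cecr2 no longer passed, at log2 changes of -0.28, -0.20, -0.25, -0.32, -0.20 and -0.38. Nr1d1 was then at -2.26 and Bcl6b at -1.0, and both passed.

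**Figure D1:**
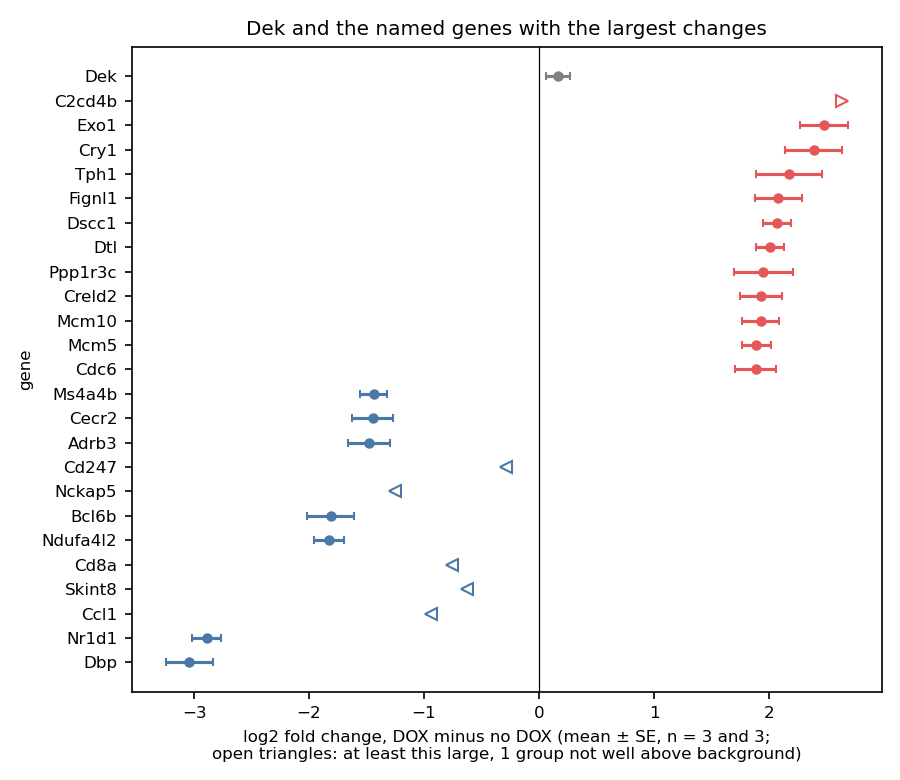
Log2 fold change (x axis, DOX minus no DOX) of Dek and of the 12 named genes with the largest rise and the 12 with the largest fall (y axis). Filled points are means with standard errors from limma (n = 3 and 3), red for genes that rose, blue for genes that fell and grey for Dek, which did not pass, with Dbp at -3.04; open triangles mark C2cd4b, Ccl1, Skint8, Cd8a, Nckap5 and Cd247, which were not well above background in 1 group, at the log2 of their bound in the processed signal.

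All 106 genes and unnamed probes that passed had 3 DOX values on 1 side of the 3 values without DOX. A change large enough to pass leaves little room for overlap, so this adds no support of its own. Of everything tested, 25.3% had such values, where chance gives 10% on average. Genes that vary together let this share depart from 10% by chance. The count of 106 fell when 1 array was left out. It was 3 without no DOX replicate 1, 3 without no DOX replicate 2 and 23 without no DOX replicate 3. It was 19 without DOX replicate 1, 51 without DOX replicate 2 and 26 without DOX replicate 3. Rises no longer outnumbered falls without DOX replicate 3 (13 and 13) or no DOX replicate 1 (1 and 2), and they were 12 against 11 without no DOX replicate 3. Of 34 named genes that passed, Nr1d1 alone passed in all 6 of those fits, and 15 passed in none of them. Among the 15 were C2cd4b, Tph1, Fignl1, Ppp1r3c, Bcl6b, Adrb3, Cecr2, Nckap5, Rad54l, Hsph1, Hsp90aa1, Cyp1b1 and Ahrr. Each of the 34 kept its direction in those 6 fits.

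Genes of DNA replication and S phase were higher with DOX as a group. All 29 measured members had a higher mean, 18 rose over all probes, 11 did not pass, and 29 rose when adjusted over the list alone. The median log2 change was 0.98 (interquartile range 0.64 to 1.45). Examples are Mcm5 (log2 1.89 ± 0.13), Mcm10 (1.93 ± 0.16), Uhrf1, which maintains DNA methylation at replication forks (1.84 ± 0.15), and the licensing factor Cdt1 (1.67 ± 0.13). The list was called by camera with an adjusted p of 1e-30, and its adjusted p = 0.222 with an estimated correlation. Camera called this list in all 10 groupings of the arrays, with 2.5e-06 as the smallest adjusted p of the others. In the DNA damage repair list 4 of 22 genes rose, none fell, and 10 rose when adjusted over the list alone. Examples are Exo1 (2.48 ± 0.21) and Rad54l (1.30 ± 0.13, and 0.53 with normexp). The median of this list was 0.39, with an adjusted p of 4.02e-08 from camera and an adjusted p = 0.222 with an estimated correlation.

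Of 13 histone genes, 0 passed over all probes and 7 rose when adjusted over the list alone. The smallest p belonged to H2ac4 (1.21 ± 0.17), H1f5 (1.29 ± 0.20), H3c13 (0.77 ± 0.19) and H2ac20 (0.45 ± 0.11). The histone median was 0.41, with an adjusted p of 0.000122 from camera and an adjusted p = 0.838 with an estimated correlation. The mitosis and G2/M list had a median of 0.08 over 27 genes, of which 0 passed over all probes and 0 when adjusted over the list alone. It was not called (adjusted p = 0.960 from camera, and adjusted p = 0.991 with an estimated correlation). The mitosis list's array means were -0.125, -0.26 and 0.354 for no DOX replicates 1 to 3 and 0.135, 0.214 and -0.319 for DOX replicates 1 to 3. Replicate 3 of each group thus ran against the others. Camera called this list in 7 of the 10 groupings of the arrays, the real one not among them (smallest adjusted p 3.64e-20). Its members with the smallest p were the checkpoint kinase gene Bub1 (log2 0.68 ± 0.20) and the centromere motor gene Cenpe (-0.68 ± 0.23).

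Clock genes changed in both directions. Of 19 measured members of the circadian list, 2 rose, 3 fell and 14 did not pass over all probes, and 6 rose and 6 fell when adjusted over the list alone. The risers were Cry1 (2.39 ± 0.25) and Nfil3, a repressor of Dbp target genes (1.87 ± 0.13, adjusted p = 0.0116). Besides Dbp and Nr1d1, the third that fell was Nr1d2 (log2 -1.06 ± 0.13, adjusted p = 0.0406), named after its value was seen. The list had no called net direction (median -0.10, adjusted p = 0.575 from camera, and adjusted p = 0.945 with an estimated correlation). A test for change in either direction gave an adjusted p of 9.69e-05 (fry), and the same test called 22 of the 46 lists. The labels used here do not give the hour at which tissue was taken.

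**Figure D2:**
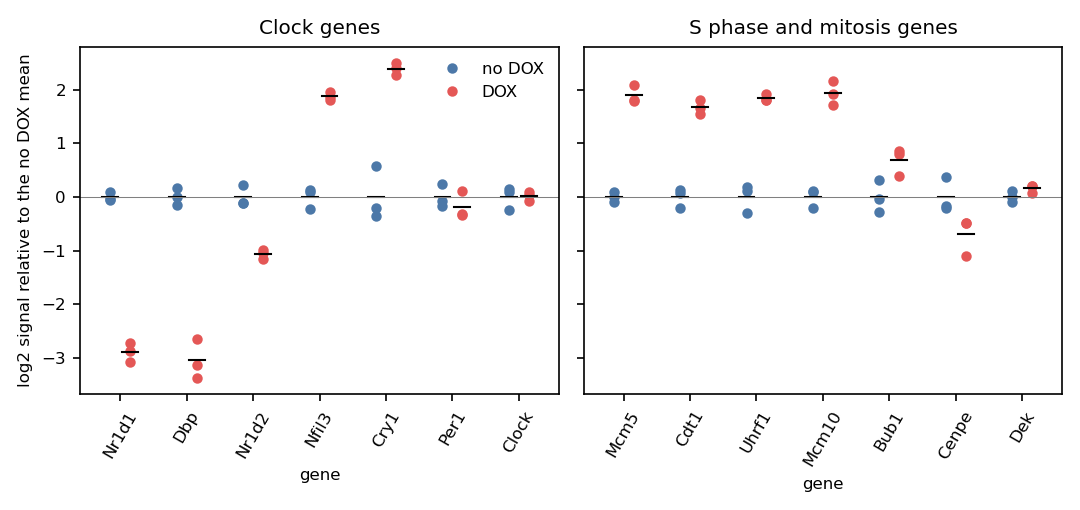
Normalised log2 signal of each array (y axis, relative to the mean of the 3 arrays without DOX) for clock genes (left) and for S phase and mitosis genes with Dek (right). Points are single arrays, blue without DOX and red with DOX, and black lines are group means; Nr1d2, Per1 and Clock were picked for display after their values were seen, and the DOX mean lies at -2.89 for Nr1d1 and at 1.87 for Nfil3.

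In the ER stress list all 18 members had a higher mean with DOX. Creld2 alone rose over all probes, and 13 rose when adjusted over the list alone. Next by p were the chaperone genes Hsp90b1 (log2 0.93 ± 0.13, adjusted p = 0.0511), Hyou1 (1.38 ± 0.19) and Sdf2l1 (1.56 ± 0.22). The ER stress median was 0.65, with an adjusted p of 1e-10 from camera and an adjusted p = 0.693 with an estimated correlation. Another grouping of the same arrays gave this list a smaller adjusted p (5.37e-12). In the salivary gland list 7 of 16 members had a higher mean and 9 a lower one, and 0 passed over all probes. Its members Bhlha15 (1.82 ± 0.28) and Lpo (2.55 ± 0.46) were higher without passing. The largest changes in size were those of Bpifa2 (6.51 ± 1.64), Klk1 (-4.22 ± 1.92) and Car6 (4.16 ± 0.96). These 3 were named after their values were seen and did not pass either. Car6 was well above background on 2 of the 3 arrays without DOX. In the B and plasma cell list 4 of 7 members had a higher mean and 3 a lower one. That list was not called (adjusted p = 0.575 from camera). Its members with the smallest p, Derl3 (2.36 ± 0.39) and Mzb1 (0.59 ± 0.17), were higher without passing over all probes. In the heat shock list 2 of 12 rose, Hsph1 (1.25 ± 0.13, adjusted p = 0.0241) and Hsp90aa1 (1.24 ± 0.15, adjusted p = 0.0406). Adjusted over the list alone 7 rose, including Dnaja1 (0.99 ± 0.14) and Hspa1a (1.24 ± 0.21). The heat shock median was 0.57, with an adjusted p of 1.9e-07 from camera and an adjusted p = 0.482 with an estimated correlation. The integrated and mitochondrial stress response list had a median of 0.42 over 23 genes, of which 18 had a higher mean and 5 a lower one. Its adjusted p was 0.000648 from camera, and its adjusted p = 0.222 with an estimated correlation. Over all probes 0 of its members passed, and 11 rose when adjusted over the list alone. These were led by the amino acid transporter gene Slc7a5 (0.86 ± 0.17, with another tested probe at -0.03), Cth (0.53 ± 0.11), Slc3a2 (0.68 ± 0.16) and Gdf15 (0.98 ± 0.23).

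In the list of the xenobiotic and aryl hydrocarbon response, 7 of 10 members had a higher mean with DOX and 3 a lower one. Over all probes 2 rose, and 6 rose when adjusted over the list alone. Cyp1b1, a cytochrome P450 gene, rose by log2 1.56 ± 0.16 (adjusted p = 0.0231). The gene of the receptor's repressor, Ahrr, rose by 1.51 ± 0.17 (adjusted p = 0.0327), and by 0.73 with normexp. Cyp1a1 was higher by 4.68 ± 0.81 and Cyp2e1 by 0.86 ± 0.23, and neither passed over all probes (adjusted p = 0.0777 and 0.141). Cyp1a1 was well above background on 1 of the 3 arrays without DOX, and with normexp it was higher by 1.95 and passed (adjusted p = 0.0334). The list's median was 0.70, with an adjusted p of 0.00232 from camera and an adjusted p = 0.482 with an estimated correlation. The NRF2 list had a median of 0.20 over 23 genes (adjusted p 0.0136 from camera, and adjusted p = 0.928 with an estimated correlation). Over all probes 0 of them passed. Adjusted over the list alone 2 rose, Txnrd1 (0.76 ± 0.12) and Srxn1 (0.89 ± 0.17). Slc7a11 (1.60 ± 0.47) and Gstp1 (0.54 ± 0.17) did not pass. The NRF2 call was lost without no DOX replicate 1, no DOX replicate 2 or DOX replicate 3 (adjusted p = 0.0628, 0.0816 and 0.151).

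Immune lists moved in different directions. In the T and NK cell list Cd8a fell and 17 of 18 members did not pass. Adjusted over the list alone 2 fell, Cd8a and Ccl5 (log2 -0.71 ± 0.14). Cd28 (-0.35 ± 0.10) and Zap70 (-0.49 ± 0.17) did not pass. The list's median was -0.33, with an adjusted p of 0.00555 from camera and an adjusted p = 0.838 with an estimated correlation. Its call was lost without DOX replicate 3 (adjusted p = 0.0530) and with array weights (adjusted p = 0.0642). The interferon response list had a median of -0.58, and 30 of 31 members were lower. Over all probes 0 passed, and 3 fell when adjusted over the list alone. These were Zbp1 (-1.07 ± 0.23), Oas2 (-1.46 ± 0.32) and Ifih1 (-0.72 ± 0.17), and Irf9 followed at -0.61 ± 0.16. The interferon list's adjusted p was 1.86e-07 from camera, and its adjusted p = 0.882 with an estimated correlation. Camera called it in 7 of the 10 groupings of the arrays, and another grouping gave a far smaller adjusted p (1.6e-35). The interferon list's mean in DOX replicate 2 (0.15) lay above that in no DOX replicate 2 (-0.05).

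The antigen presentation list had a median of -0.20 over 16 genes (adjusted p 0.0133 from camera, and adjusted p = 0.838 with an estimated correlation). Tap2 was at -0.49 ± 0.11, H2-Q7 at -0.37 ± 0.10, H2-T23 at -0.35 ± 0.10 and H2-D1 at -0.32 ± 0.13. None of the members passed over all probes, and 0 when adjusted over the list alone. Without no DOX replicate 3 or DOX replicate 3 the call was lost (adjusted p = 0.0893 and 0.0774), as it was with array weights (adjusted p = 0.151). The macrophage list was higher by a median of 0.23 over 23 genes (adjusted p 0.0475 from camera, and adjusted p = 0.928 with an estimated correlation). Over all probes 0 passed. The lysozyme genes Lyz2 (1.03 ± 0.17) and Lyz1 (1.09 ± 0.22) rose when adjusted over the list alone. Fcgr1 (1.05 ± 0.30, well above background on 2 of the 3 arrays without DOX) and Retnla (-0.87 ± 0.29) did not pass. The macrophage call was lost without no DOX replicate 2, DOX replicate 1 or DOX replicate 2 (adjusted p = 0.211, 0.0980 and 0.366). It was also lost with normexp (0.0691), no filter on dim probes (0.0941), the filter on all 6 arrays (0.0920) and the replicate block (0.0987).

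The keratinocyte alarm and antimicrobial list had a median of 0.75 over 16 genes, of which 0 passed over all probes and 0 when adjusted over the list alone. Defb1 was at log2 1.08 ± 0.28, S100a9 at 1.65 ± 0.75, Il1f6 at 0.68 ± 0.32 and Sprr2d at 1.97 ± 0.93. DOX replicate 1 stood apart with a list mean of 1.60, against 0.02 and -0.25 in the other DOX arrays. The neutrophil list, which shares 4 members with it, also had its highest mean in DOX replicate 1 (1.08, against 0.02 and -0.45), with Ltf at 1.51 ± 0.58 and the shared S100a9; it was not called (adjusted p = 0.643). The keratinocyte alarm call (adjusted p 0.00383 from camera, and adjusted p = 0.909 with an estimated correlation) was lost without DOX replicate 1 (median 0.28, adjusted p = 0.0569). The basal keratinocyte list had a median of -0.29 over 20 genes (adjusted p 0.00383 from camera, and adjusted p = 0.882 with an estimated correlation). None of the members passed over all probes, and 4 fell when adjusted over the list alone. They were Dlk2 (-0.61 ± 0.11), the neurotrophin receptor gene Ngfr (-0.85 ± 0.16), Dst (-1.14 ± 0.27) and the integrin gene Itga6 (-0.49 ± 0.13). The other 3 tested probes of Dst lay at -0.06, -0.07 and -0.28. The basal call was lost without no DOX replicate 3 (adjusted p = 0.0893).

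The Notch list, which holds ligands and receptors as well as targets, had a median of -0.24 over 12 genes (adjusted p 0.0135 from camera, and adjusted p = 0.459 with an estimated correlation). Over all probes 0 passed, and the ligand gene Dll1 (-0.58 ± 0.13) fell when adjusted over the list alone. The ligand gene Jag1 (-0.46 ± 0.15) and the receptor genes Notch1 (-0.63 ± 0.23) and Notch3 (-0.29 ± 0.14) did not pass, and neither did any target, such as Hes1 (-0.42 ± 0.26, named after its value was seen). The Notch call was lost without DOX replicate 3 (adjusted p = 0.0613). The fibroblast and collagen list had a median of -0.15 over 25 genes (adjusted p 0.00555 from camera, and adjusted p = 0.928 with an estimated correlation). Thy1 (-0.74 ± 0.18), Col3a1 (-1.19 ± 0.29), Fap (-0.67 ± 0.20) and Fbn1 (-0.75 ± 0.24) did not pass, and 0 members did when adjusted over the list alone. The fibroblast call was lost without no DOX replicate 1, DOX replicate 1 or DOX replicate 3 (adjusted p = 0.0636, 0.0508 and 0.128).

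The hypoxia and glycolysis list had a median of -0.11 over 27 genes (adjusted p 0.0469 from camera, and adjusted p = 0.882 with an estimated correlation). None of the members passed over all probes. Ankrd37 (-0.69 ± 0.12) and the oxygen sensor gene Egln3 (-0.68 ± 0.13) fell when adjusted over the list alone, and Pdk1 (-0.41 ± 0.11) and Ndrg1 (-0.45 ± 0.12) did not pass. The hypoxia call was lost without no DOX replicate 2 or DOX replicate 3 (adjusted p = 0.196 and 0.210), and with the mean of all probes of a gene (0.0940). The mitochondrial ribosome list had a median of 0.18 over 26 genes (adjusted p 0.00381 from camera, and adjusted p = 0.928 with an estimated correlation). Mrps22 was at 0.35 ± 0.10, Mrps2 at 0.41 ± 0.13, Mrps7 at 0.34 ± 0.11 and Mrps27 at 0.45 ± 0.17, and 0 members passed over all probes or adjusted over the list alone. This call was lost without DOX replicate 2 (adjusted p = 0.0761).

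In all, camera with a preset inter-gene correlation of 0.01 called 18 of 46 lists, 11 higher and 7 lower. With an estimated correlation 0 of them held, and 4 lists had an unadjusted p under 0.05. Fry, which asks whether the genes of a list move 1 way on balance and sets them against no other genes, called 6 of the 46 lists. They were DNA replication and S phase (adjusted p = 0.00202), DNA damage repair (0.00332), heat shock (0.0199), the integrated and mitochondrial stress response (0.000558), the xenobiotic list (0.0419) and the Notch list (0.0199). Regrouping the same 6 arrays in other ways into 3 and 3 called up to 25 lists, so the number of lists called does not set the real groups apart from other groupings of these mice. For 5 of the 18 lists the real grouping gave the smallest p of the 10 groupings. They were DNA replication and S phase, DNA damage repair, heat shock, the integrated and mitochondrial stress response, and the Notch list. Camera called these in 10, 6, 5, 1 and 2 of the 10 groupings, the real one included, and the other 13 in 3 to 9. With the slide row as a block, which leaves DOX replicate 1 alone against the arrays without DOX, the calls of NRF2, Notch, T and NK cell, antigen presentation, basal keratinocyte, hypoxia and macrophage lists were lost. The other 28 lists were not called. Among them were fast and slow skeletal muscle, taste bud, endothelium, adipocyte, p53 targets and cytosolic ribosomal proteins. Of the 28, 13 were called in at least 1 other setting. Fast skeletal muscle was called higher without no DOX replicate 2 (adjusted p = 0.0130), and endothelium lower without no DOX replicate 3 or DOX replicate 2 (0.0204 and 0.0439). Cytosolic ribosomal proteins were called lower with quantile normalization or without no DOX replicate 1 (0.0307 and 0.0458). DEK-associated chromatin factors were called higher without no DOX replicate 3 (0.0394).

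**Figure D3:**
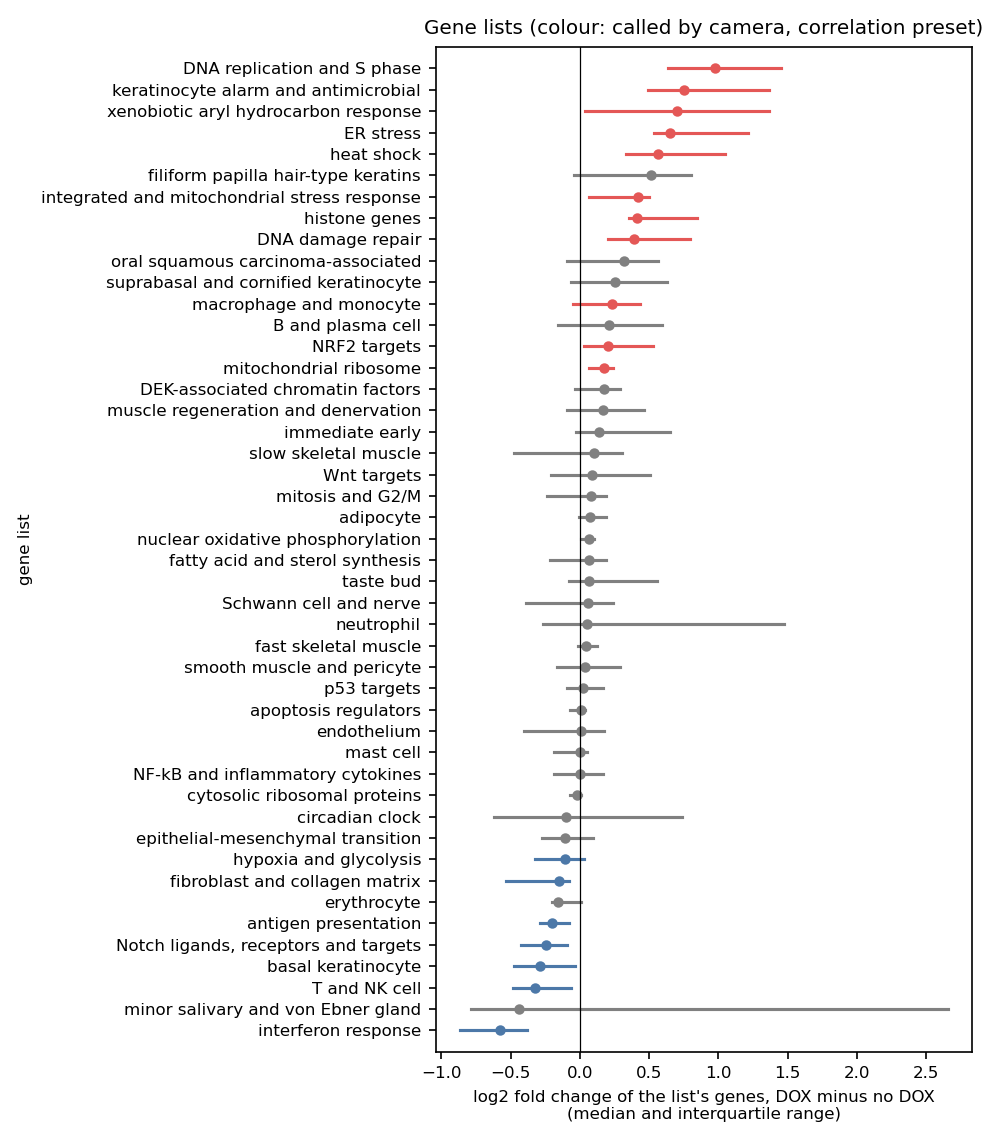
Median (point) and interquartile range (line) of the log2 fold change (x axis, DOX minus no DOX) of the members of each of 46 gene lists (y axis). Red and blue mark lists called higher or lower by camera with the preset correlation, of which 0 held with an estimated correlation, and grey marks lists not called; the S phase list lies highest with a median of 0.98 and the interferon list lowest at -0.58.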

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

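The slide row as a block and the list background with unnamed probes were chosen after seeing the data. The count of 106 genes and unnamed probes was within 1.5 times under quantile normalization, median scaling, the value table, the filter on all 6 arrays and the mean of all probes of a gene (91 to 115). It was 246 with normexp on the median signal (79 of the 106 among them), 192 with trend and robust variance (94 shared), 484 with array weights (all 106 shared), 747 at an adjusted p under 0.1, and 625 for changes of at least 2-fold with no overlap and no test, where chance separates the groups for 10% of genes. It was 1 with no filter on dim probes (33 of 34 named genes lost), 32 with the slide row as a block (11 shared), a fit that rests on DOX replicate 1 alone, and from 3 to 51 when 1 array was left out. With the replicate block it was 0 in limma, with 4732 at an unadjusted p under 0.05. Same-numbered arrays deviated with correlations of -0.12, -0.01 and 0.01, which show no pairing over all probes. Deviations of 3 arrays per group cannot exclude a pairing. The fast skeletal muscle list was highest in replicate 2 and lowest in replicate 3 in both groups. The keratinocyte alarm list was highest in replicate 3 without DOX and in replicate 1 with DOX. The cause was not tested for any of these counts. Higher calls were 68.9% of the main count, 61.3% in the value table, 76.3% with the filter on all 6 arrays, 60.7% with array weights, 56.0% at an adjusted p under 0.1 and 33.3% to 76.5% with 1 array left out. Dek stayed above 0 and short of the threshold throughout, at log2 0.11 to 0.22 with adjusted p from 0.289 to 0.724; it has 1 probe, so other probes could not be tried. Lists called numbered 16 to 19 under the other planned settings with the preset correlation, 14 to 20 with 1 array left out, 15 with the slide row as a block (11 of the 18 among them, with NRF2, Notch, T and NK cell, antigen presentation, basal keratinocyte, hypoxia and macrophage lost, and NF-kB, immediate early, neutrophil and carcinoma-associated lists gained), 17 with unnamed probes in the background (hypoxia and glycolysis lost, adjusted p = 0.0778) and 0 with an estimated correlation. The NF-kB list reversed to a call lower without DOX replicate 1 (median -0.23, adjusted p = 0.0252); its medians with 1 array left out ran from -0.23 to 0.145, and it was called higher with the slide row as a block (0.40), again from DOX replicate 1 alone. Leaving out 1 array also added calls of Schwann cell, oxidative phosphorylation, hair-type keratin, suprabasal keratinocyte, immediate early, carcinoma-associated and erythrocyte lists (adjusted p from 0.000732 to 0.0422). No slide or scan block could be fitted. Dim probes limit the size of falls and rises. With normexp the falls of Ccl1, Skint8, Cd8a, Nckap5, Cd247 and Cecr2 shrank to between -0.38 and -0.20. The rises of Cry1, Cdc6, Dscc1 and C2cd4b shrank as well and still passed.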

Other observations

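The tests of explanations in this part were chosen after the results were seen, except the regroupings of the arrays. The salivary gland and taste bud lists were not called (adjusted p = 0.957 and 0.246). In the salivary gland list, 4 of 16 members rose when adjusted over the list alone and none over all probes, among them Bhlha15, a secretory cell transcription factor (log2 1.82 ± 0.28), and Lpo, a secreted peroxidase (2.55 ± 0.46), with a list median of -0.44 and mean of 0.80 that differ in sign; no DOX replicate 2 had the lowest list mean (-1.63). In the taste bud list, 3 of 18 rose when adjusted over the list alone, led by Gng13 (1.06 ± 0.15) and the sweet receptor gene Tas1r2 (1.17 ± 0.25). Of the unnamed probes, A_55_P1967548 rose by 5.49 ± 0.61 on the log2 scale and A_51_P376778 was at least 11.7-fold higher, and A_30_P01026037 was at least 6.30-fold lower in the processed signal; these were singled out after their values were seen.

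Regrouping the arrays gave 106 genes and unnamed probes for the real groups and at most 0 for the other splits, so 1 of the 10 splits reached the real count; with limma the other splits had 557 to 2650 at an unadjusted p under 0.05, against 4891. For lists, 7 of the 10 splits called at least the real 18, with up to 25. With 10 splits no share under 0.05 can be reached. Each other split also puts DOX and no DOX arrays together in both of its groups. A real difference would then add to the spread within groups and lower the gene count, so the contrast of 106 with 0 is partly built in.

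Clock genes differed between the groups, and no explanation weighed here is excluded. A different tissue makeup of the pieces stays open. The members of the salivary gland list went both ways around a median of -0.44, with an interquartile range of 3.44. The called clock genes had a median size of 2.39. The median of every other cell type list lay below that size by more than its own interquartile range. The neutrophil list came nearest, 0.594 short after its interquartile range was added. The 5 called genes were picked because they passed, so they set a high bound. The value of 2.39 is that of Cry1, which was well above background on 1 of the 3 arrays without DOX. Falling short of this bound therefore excludes none of those cell types. Textbook targets of ROR elements (5 genes, mean log2 change 1.21) and of E-boxes (14 genes, -0.59, with Per2, Wee1 and Usp2 higher) moved apart by 1.80 ± 0.25 (SE), but these arms were set after the values were seen and hold the 5 called genes; without those the difference was 0.71 ± 0.23 (SE), with 0.59 and -0.12 for the arms. Collection of the groups at different hours is a candidate explanation that these values leave open. An action of Dek or DOX on the clock predicts the same and stays open, because no collection hour or DOX-only group was analysed here. The Dek difference of 0.165 ± 0.107 (SE) cannot decide this. Its probe may lie outside the transgene's part, and it does not bear on an action of DOX itself.

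S phase genes were higher with DOX. A larger share of cells in all phases of division, raising the S phase and mitosis lists about equally, is argued against. The change of the S phase list exceeded that of the mitosis list by 1.06 ± 0.22 (SE). Per array, the S phase mean minus the mitosis mean was at most -0.368 without DOX and at least 0.275 with DOX. That separation was fixed by the S phase list, whose groups lay 0.972 apart, while the mitosis means ran only from -0.319 to 0.354. The mitosis list alone varied between mice within each group, so a smaller rise of it is not excluded. The basal keratinocyte list had a median of -0.291, with 15 members lower and 5 higher and array means that overlapped between the groups. This argues against basal keratinocytes rising as much as the S phase list, and a smaller rise is not excluded. Array position stays open: the change was 1.17 ± 0.09 (SE) with the slide row as a block, against 1.08 without it, but this rests on DOX replicate 1 alone. An action of Dek or DOX on S phase genes stays open: the lowest DOX array lay 0.972 above the highest array without DOX, and the effects of Dek, DOX, array position and collection hour cannot be told apart in this design. Entry into S phase follows the daily clock in oral epithelium, so both patterns may share the collection hour as a source, which these values do not test.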
